A study of Mus musculus with 6 samples.

How the data were processed

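RNA was measured on 6 CodeLink 20K mouse expression arrays, 3 of fibroblasts lacking p38α (KO) and 3 of wild-type fibroblasts (WT), all carrying H-Ras G12V. Per the labels, each array was hybridised with a culture's RNA in Cy5 and a pool of RNA of the same genotype in Cy3. Each file, however, holds a single channel. The values were therefore analysed as 1-colour intensities, as had been written down for that case before the data were examined. They were taken as those of the cultures, since the name inside each file is that of a culture. If the channel were instead that of a pool, the arrays of a genotype would be repeats of 1 RNA. No second channel was available, so neither the Cy5 to Cy3 ratios nor the difference between the pools could be computed.

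The deposited scanner files give a mean and a median spot intensity and a local background intensity for each spot. In every file the deposited expression value, also an intensity, equals the mean spot intensity minus the median background. The authors' normalized value in the same files is that intensity divided by 1 constant per array. Per the submitters' processing notes, limma was used, with no version stated. The software that read the slides is not given in the sources used here. The authors' value table holds the same normalized intensities. Its columns for KO replicates 2 and 3 hold each other's file values: 99.7% of their 19800 rows were equal to 6 decimals after exchanging them. The names inside these 2 files are exchanged against the sample titles in the same way. Replicate names here follow the titles, and the groups are the same under either naming. The column medians of that table were 0.961 to 0.974, and 19674 of its rows were matched to a probe by their values.

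Background was corrected with normexp, offset 50, on the mean spot and median background intensities in limma 3.58.1 under R 4.3.3. Spots marked masked, contaminated or irregular were left out, saturated spots were kept, and control spots were dropped after normexp. The log2 values of 19801 gene probes were then quantile normalized between arrays. KO and WT were compared for 19604 probes with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all of these probes and a threshold of 0.05 on the adjusted p. The offset pulls log2 differences of dim probes toward 0. Simulated arrays were made from the WT and KO values, with 50 probes changed at each fold among 19604 tested. The changed probes were drawn only from those whose mean signal exceeded a cut well above the median of every array (15.9 to 21.7). All probes were given the same log2 noise. Of these brighter probes, 34.0% of the 1.2-fold changes and 100% of the 1.5-, 2- and 4-fold changes were called. Recovery among dim probes was not measured. The 4-fold changes were estimated at a median log2 difference of 1.70. Of 186 calls 19 were false (10.2%), a share above the threshold of 0.05.

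A probe was taken as above background by the scanner software's own mark. Where a gene was near background on every array of 1 group, its difference is given as "at least N-fold". That bound sets the brighter group's mean of normalized log2 values against the dim group's mean of, per array, the higher of the lowest signal among probes above background and the probe's own. Where both groups were near background, no fold is given.

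Probes were named through unversioned RefSeq accessions, or else a unique synonym, in a gene table of mouse assembly GRCm38.p6. In all, 10813 probes were named, 10712 of them by accession and 101 by synonym, for 10634 genes, and 8988 stayed unnamed. The array's own build is not given in the sources used here, so no coordinates are printed, and that table served only for names, chromosomes and neighbours. Mapk14 and Hras are named always. Also named are the 12 genes with the highest and the 12 with the lowest difference among those past the threshold, without overlap between groups and above background on all 3 arrays of the higher group. From each of 25 gene lists up to 4 members with the smallest adjusted p are named, or 2 where none passed. The result of 1 gene that these rules name is not reported here. These naming rules, the 25 lists and the tests between KO and WT of probes and lists were fixed before the data were examined. For list tests each gene was represented by its brightest probe. Measured members include genes near background on every array, and for those a missing call does not show that the gene was unchanged. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over 24 lists. The 4 measured sex-linked genes were too few for that test.

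The labels call the 3 cultures of each genotype biological replicates, without saying whether they came from separately derived lines, and give 1 pool identifier per genotype, although the names of the WT pools differ in their last member. The p-values therefore measure only the spread between these cultures, and a difference between founder lines could not be separated from one between genotypes. The file headers give 1 day for all 6 arrays and a separate array number for each, so no slide or scan batch could be fitted. Alternatives covered the background correction, the scaling, filters on dim probes, the eBayes options, array weights, a 2-fold minimum, the authors' table, the replicate number as a block and each array left out.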

Results

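Genome-wide RNA levels were compared between mouse embryo fibroblasts lacking p38α (KO, n = 3 cultures) and wild-type fibroblasts (WT, n = 3 cultures). Both had been immortalised spontaneously by serial passage and stably transduced with the oncogene H-Ras G12V, and were harvested after 72 h of growth while still below confluence. p38α, encoded by Mapk14, is a stress-activated protein kinase. Each culture was hybridised to 1 array, and the number of arrays limits the precision of every value. Between 8677 and 10232 of 19801 gene probes were above background per array, the fewest on KO replicate 3 (43.8%) and the most on KO replicate 1 (51.7%). KO replicate 3 also had the highest median local background, 61 intensity units against 49 to 53 on the other arrays. Correlations of log2 values across probes were 0.996 to 0.997 between WT arrays, 0.986 to 0.996 between KO arrays and 0.951 to 0.963 between the groups. Probes are not independent replicates.

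The comparison addressed which genes depend on p38α in cells transformed by oncogenic Ras. Mapk14 itself was lower in KO, at a normalized log2 signal of 6.07 ± 0.12 against 7.01 ± 0.06 in WT (SD, n = 3), a difference of -0.94 (SE 0.07, limma adjusted p = 7.8e-05). Background-subtracted Mapk14 intensities were 17.6, 18.6 and 8.35 in KO replicates 1, 2 and 3, and 60.8, 70.6 and 68.8 in WT. Only KO replicate 2 was marked above background, against all 3 WT arrays. The size of the difference depends on the offset added to dim signals: with offset 0 it was -2.24 (adjusted p = 0.0037). Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so whether it tests the deletion itself is open. The Hras probe differed by 0.31 (SE 0.13, adjusted p = 0.14), with 10.58 ± 0.24 in KO and 10.27 ± 0.14 in WT. Whether it detects the transduced copy is likewise unknown. Hras passed the threshold under median scaling (0.52, adjusted p = 0.0050) and without KO replicate 1 (0.42, adjusted p = 0.041).

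Over the whole array, 4421 of 19604 probes passed the threshold, 2047 higher and 2374 lower in KO. Of these, 692 differed at least 2-fold, 423 higher and 269 lower, and the median fold of all calls was 1.43. Counted once per named gene, 1382 genes were higher and 1372 lower among 10558. KO and WT values did not overlap for 36.0% of the probes, where chance gives 10%. With median scaling in place of quantile normalization, 64.1% of the calls were higher in KO, against 46.3% here.

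The gene raised most in KO was Hba-a1, the alpha chain of adult haemoglobin. Its log2 signal was 13.86 ± 0.09 in KO and 6.67 ± 0.06 in WT (SD, n = 3), which is 146-fold higher (SE 0.07 on the log2 scale, adjusted p = 5.3e-09). That fold depends on the processing. Background-subtracted Hba-a1 intensities in WT were only 45.3, 45.0 and 36.9, and the offset pulls differences of such dim signals toward 0. The log2 difference was 7.19 in the reported fit and 7.07 to 8.22 over the other settings with all arrays kept. The next genes were near background in all 3 WT cultures. They were Fst, the secreted activin inhibitor follistatin, at least 44.2-fold higher, Anxa8, a calcium-dependent phospholipid-binding protein, at least 39.0-fold, and Aig1 at least 37.2-fold. Tac1, the precursor of substance P, was at least 33.1-fold higher, the Wnt modulator Dkk2 at least 23.1-fold and the urea transporter Slc14a1 at least 16.3-fold. Krt19, an intermediate filament protein of epithelia, was 31.9-fold higher and detected in 1 of 3 WT cultures. Mmp3, a matrix metalloproteinase, was 20.1-fold higher, Cryab, a small heat shock protein, 16.5-fold, Ly6a, the surface antigen Sca-1, 14.6-fold and the secreted glycoprotein Stc2 14.4-fold. Adjusted p-values of these genes were 1.84e-05 or smaller.

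Among the genes lowered most, Rsrp1 was 16.5-fold lower in KO (log2 difference -4.04, SE 0.07, adjusted p = 4.9e-08). Cxcl1, a chemokine that attracts neutrophils, was 15.1-fold lower, the inhibitory receptor Sigirr 11.5-fold (above background in 2 of 3 KO cultures), Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, 10.8-fold and the secreted serine protease Htra1 10.4-fold (2 of 3). Rhox5, a homeobox gene, was at least 12.4-fold lower, Hoxb7 at least 10.3-fold and Ces1g, a carboxylesterase, at least 7.99-fold. All 3 of these were near background in every KO culture. The lysosomal protease Ctsh was 8.40-fold lower (2 of 3) and Hoxa5 6.91-fold. Tpd52 was above background in only 1 of 3 KO cultures, so the size of its difference is uncertain, -2.75 here and -4.66 with offset 0. The adjusted p of each of these lowered genes was 4.22e-07 or smaller.

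**Figure D1:**
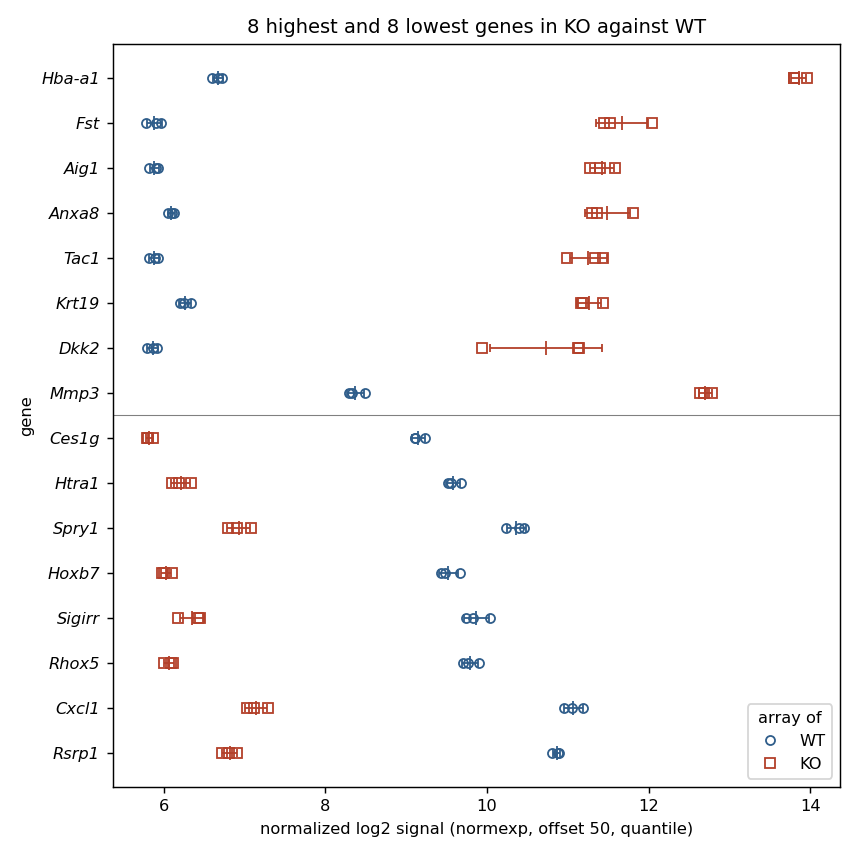
Normalized log2 signal (horizontal axis) of the 8 genes highest and the 8 lowest in KO against WT (vertical axis), with circles for the 3 WT arrays, squares for the 3 KO arrays, a tick at each mean and bars of 1 SD. KO and WT arrays do not overlap for any of these genes, and Hba-a1 has the widest gap, 7.19 log2 units.

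In the p38 pathway list, 5 of 18 measured genes were higher and 4 lower in KO (6 and 5 adjusted over the list alone). Besides Mapk14, the related kinase gene Mapk13 was lower, by 2.35-fold (adjusted p = 4.3e-04). Mapk13 is also a measured gene directly beside Mapk14 on the chromosome. Hspb1, a small heat shock protein phosphorylated downstream of p38, was 3.02-fold higher (1.59 in log2 units, 2.45 with the authors' table), and Dusp1, a phosphatase that inactivates p38 and JNK, 2.71-fold. Of the JNK pathway and AP-1 list, 4 of 18 genes passed, all lower (4 adjusted over the list alone). They were Jdp2, a repressor that partners Jun (2.34-fold), the scaffolds Mapk8ip3 (1.45-fold, lost with offset 0 at adjusted p = 0.058) and Mapk8ip1 (at least 1.17-fold, above background in 2 of 3 WT cultures), and the kinase Map3k4 (1.25-fold). The call of Map3k4 (-0.32) was lost under median scaling (-0.17, adjusted p = 0.39), with the spot median (-0.18, 0.18), with offset 0 (0.12), without KO replicate 2 (0.062) and without WT replicate 2 (0.065). Ras-ERK feedback and target genes showed 8 higher and 2 lower of 21 (8 and 4 adjusted over the list alone). Hmga2, a chromatin protein of embryonic cells, was 2.93-fold higher, the transcription factor Etv1 1.94-fold and Spry2 1.74-fold, while its relative Spry1 was lower. No list in this paragraph passed camera (adjusted p of 0.36 or more).

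Of the cell cycle and DNA replication list, 7 of 26 genes were lower and 1 was higher in KO (8 and 1 adjusted over the list alone). Replication licensing genes were among the lower ones: Cdt1 by 2.21-fold, the helicase subunit Mcm5 by 1.80-fold and the loading factor Cdc6 by 1.54-fold. Ccnb2, a mitotic cyclin, was 1.63-fold higher. The list did not pass camera (adjusted p = 0.12), except without KO replicate 1 (0.034). Without any 1 of the WT replicates 4 members were lower and 1 higher, and under median scaling, where Cdc6 lost its call, 2 were lower and 3 higher.

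Of 22 targets of p53 and inhibitors of the cell cycle, 9 were lower and 1 higher in KO, and 12 did not pass (10 and 2 adjusted over the list alone). Trp53inp1, a p53-induced nuclear protein, fell by 1.42 on the log2 scale (adjusted p = 2.0e-05) and the p53 target Zmat3 by 0.98. Cdkn2c, a CDK inhibitor, was 1.51-fold lower and Perp, a p53 target of cell junctions, at least 1.30-fold lower. The only member higher was Cdkn1a, the CDK inhibitor p21, by 2.71-fold (adjusted p = 0.0021), named here after its value was seen. The list passed camera (adjusted p = 0.027), but not with an estimated correlation (adjusted p = 0.26 with an estimated correlation). It also missed the threshold without WT replicate 3 (adjusted p = 0.053), under median scaling (0.12), with either filter on dim probes (0.055 and 0.060) and with the authors' table (0.052). The estimated correlation of this list was -0.039, below the preset 0.01.

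Apoptosis regulators went both ways, with 3 of 26 higher and 5 lower (4 and 5 adjusted over the list alone). Bok, a relative of Bcl-2, was 3.82-fold higher, the inflammatory caspase Casp4 2.46-fold (1.30 in log2 units, 2.05 with the authors' table) and the TNF receptor Tnfrsf1a 1.53-fold, while Bid, a linker of death receptors to mitochondria, was 1.27-fold lower. The list did not pass camera (adjusted p = 0.97). Without KO replicate 3 the counts were 7 higher and 6 lower, without WT replicate 1 or 3 they were 3 and 2, and under median scaling or offset 0, where Bid lost its call (adjusted p = 0.13 and 0.074), 3 and 0.

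Of 23 glycolysis and hypoxia genes, 11 were higher and 1 lower in KO, and 11 did not pass (12 and 1 adjusted over the list alone). The lactate transporter Slc16a3 was at least 5.97-fold higher, the peptide hormone adrenomedullin, Adm, at least 2.77-fold and the mitophagy receptor Bnip3 2.21-fold. Egln3, an oxygen-dependent prolyl hydroxylase, was the member lower, by 2.86-fold (adjusted p = 1.5e-06; -1.51 in log2 units, -2.49 with offset 0), and was above background in 2 of 3 KO cultures. The list passed camera (adjusted p = 3.0e-04) but not with an estimated correlation (adjusted p = 0.20 with an estimated correlation), nor with the authors' table (0.052). Its estimated correlation was -0.017, below the preset 0.01. Among 17 cholesterol synthesis genes 7 were higher, none lower, and 10 did not pass (10 and 1 adjusted over the list alone). Nsdhl was 2.15-fold higher, Ebp 1.70-fold, Fdft1 1.61-fold and Idi1 1.29-fold, all enzymes of that pathway. Idi1 (0.37) lost its call with offset 0 (adjusted p = 0.097) and lay at 0.56 under median scaling. This list passed camera (adjusted p = 0.0027) but not with an estimated correlation (adjusted p = 0.24 with an estimated correlation), nor with the authors' table (0.052). Without KO replicate 3, the array with the fewest probes above background, 12 of its members were higher and 1 lower. The estimated correlation of the cholesterol list was 0.0085, also below the preset 0.01.

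Antioxidant and glutathione genes were split, 8 of 29 higher and 6 lower (10 and 8 adjusted over the list alone), but 2 and 4 with offset 0 and 10 and 5 under median scaling. The quinone reductase Nqo1 was at least 1.58-fold higher and the glutathione transferase Gsto1 1.88-fold higher, whereas its relative Gstm2 was 2.50-fold lower and haem oxygenase, Hmox1, 2.04-fold lower. Of 19 genes of the unfolded protein and amino acid stress list, 8 were higher and 3 lower (9 and 4 adjusted over the list alone). Besides Stc2, the chaperones Dnajc3 (2.68-fold), Dnajb9 (at least 1.70-fold) and Sdf2l1 (1.62-fold) were higher. Genes of the stress list lay a median of 0.16 higher on KO replicate 3 than on the other KO arrays, the largest shift of the 25 lists, and without that array 9 were higher and 4 lower. Neither list passed camera (adjusted p = 0.91 and 0.11), but the stress list did under median scaling (0.027) and without KO replicate 2 (0.041). Both of these used the preset correlation. With its estimated correlation of 0.12, the stress list had an adjusted p of 0.48 in camera over all 6 arrays.

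Genes of the extracellular matrix changed in both directions, 12 of 34 higher and 10 lower (13 and 11 adjusted over the list alone). Vcan, the proteoglycan versican, was 4.16-fold higher in KO and Tnc, tenascin C, 4.13-fold, while Efemp1, a fibulin, was 6.08-fold lower and the small proteoglycan Ogn at least 2.43-fold lower. Matrix proteases and their inhibitors were more often higher, 11 of 35, than lower, 4 (12 and 4 adjusted over the list alone). With Mmp3, the collagenase Mmp13 was 3.20-fold higher, and with Htra1, the gelatinase Mmp2 was 2.12-fold lower (1.68 and -1.08 in log2 units, 2.78 and -1.70 with offset 0). Of the adhesion and surface receptor list 7 of 26 were higher and 4 lower (7 and 4 adjusted over the list alone). The tetraspanin Cd9 was 4.90-fold higher, Cdh13, a cadherin, at least 1.96-fold, and Sema3c, a guidance cue, 1.67-fold (0.74 in log2 units, 1.36 with offset 0), while Vcam1, a leukocyte adhesion molecule, was at least 1.59-fold lower. None of the 3 lists passed camera (adjusted p of 0.11 or more). Near background on every array were 8 of 34 matrix, 13 of 35 protease and inhibitor and 11 of 26 adhesion genes.

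Secreted signals also differed in both directions. Of 31 cytokine and chemokine genes 8 were higher and 9 lower (8 and 10 adjusted over the list alone). The chemokine Ccl7 was 3.67-fold higher, whereas with Cxcl1 the chemokines Cxcl5 (5.28-fold; -2.40 in log2 units, -3.77 with the authors' table) and Cxcl12 (at least 2.74-fold) were lower. Growth factors, their receptors and binding proteins showed 14 of 42 higher and 6 lower (14 and 7 adjusted over the list alone). After Fst, the matricellular protein Ccn3 was 3.85-fold higher, the EGF receptor ligand Areg 3.02-fold (1.59 in log2 units, 2.63 with offset 0) and the lymphangiogenic factor Vegfd 2.50-fold. The interferon response list had 3 of 32 higher and 1 lower (3 and 1 adjusted over the list alone): Ly6e (4.13-fold), Ifitm3 (1.90-fold) and Ifit3 (at least 1.32-fold, above background in 2 of 3 KO cultures, lost without WT replicate 3 at adjusted p = 0.053 and with the authors' table at 0.055) were higher, and the transcription factor Irf1 was 1.56-fold lower. The adjusted p of camera was 0.12 or more for these lists. Near background on every array were 19 of 32 interferon, 9 of 31 cytokine and chemokine and 10 of 42 growth factor genes.

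Markers of other cell types changed in part. In the muscle and contractile list 5 of 22 genes were higher and 2 lower (5 and 2 adjusted over the list alone), with Ckb, a creatine kinase, at least 5.69-fold, Csrp2 4.03-fold, calponin, Cnn1, at least 3.17-fold and Csrp1 2.20-fold higher. Of 16 fat cell genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone). The fatty acid binding protein Fabp4 was 10.5-fold higher, the transcription factor Cebpd 2.43-fold and the desaturase Scd2 1.69-fold, while Fabp5 was 2.58-fold lower. Among 15 epithelial genes Krt19 and Krt18, also a keratin of simple epithelia (at least 2.16-fold), were higher, and Lamb3 was called lower with both groups near background and lost that call without any of 3 single arrays (2 and 1 adjusted over the list alone). The neural genes Gap43 (3.13-fold; 1.65 in log2 units, 2.58 with the authors' table), Nefm (at least 2.39-fold) and Stmn2 (at least 1.72-fold) were higher, 3 of 14 measured (3 adjusted over the list alone). Hba-a1 was the only called member of 15 macrophage and blood cell markers (1 adjusted over the list alone). None of 10 endothelial genes passed (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05 in limma), and the 2 with the smallest p, Tek (0.14, adjusted p = 0.29) and Cdh5 (-0.10, adjusted p = 0.32), were near background in both groups. Tek passed without KO replicate 3 (adjusted p = 0.042), without background correction (0.037) and with array weights (0.045). No marker list passed camera (adjusted p of 0.12 or more). Near background on every array were 12 of 15 macrophage and blood, 11 of 15 epithelial and 9 of 10 endothelial markers. So were 7 of 14 neural, 7 of 16 fat cell and 9 of 22 muscle and contractile genes.

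Of 16 imprinted genes 1 was higher and 4 lower (1 and 4 adjusted over the list alone), and 3 and 5 without KO replicate 3. Snrpn was 2.24-fold lower, Dlk1 at least 1.92-fold and Ndn at least 1.67-fold, while Phlda2 was at least 1.72-fold higher. The adjusted p of camera was 0.36. The 4 sex-linked genes measured did not pass, over all probes or adjusted over the list alone (0 at an unadjusted p under 0.05 in limma), with Eif2s3x at a difference of 0.08 (adjusted p = 0.66) and Eif2s3y at -0.08 (adjusted p = 0.56) and near background in both groups.

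Hox genes mark the position of a cell along the body and limb axes. Of the list of 32 Hox and limb position genes, 9 were higher and 11 lower in KO (9 and 12 adjusted over the list alone), with a camera adjusted p of 0.29. Of 7 Hox genes in the paralog groups 10 to 13, 6 were higher and 1, Hoxb13, lower. Of 21 in the groups 1 to 9, 2 were higher, Hoxa7 and Hoxd9, 9 lower, and 10 did not pass. Hoxa6, Hoxa9, Hoxb4, Hoxb8, Hoxc4, Hoxd1 and Hoxd3, which did not pass, were near background in both groups. So was Hoxc5, called lower at a log2 signal of 5.91 in KO against 6.11 in WT. Hoxa13 (6.08 against 5.76) and Hoxd9 (6.17 against 5.83) were called higher. Both were near background in WT, with KO values too low for a fold bound. With Hoxa5 and Hoxb7, Hoxc9 was at least 3.54-fold and Hoxc8 at least 3.20-fold lower, all with adjusted p of 1.52e-06 or smaller. On the other side Hoxd11 was at least 7.03-fold higher, Hoxa11 at least 2.51-fold and Hoxa10 at least 2.51-fold. The grouping was made, and these 3 genes, the 3 exceptions and the genes near background were named, after their values were seen.

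**Figure D2:**
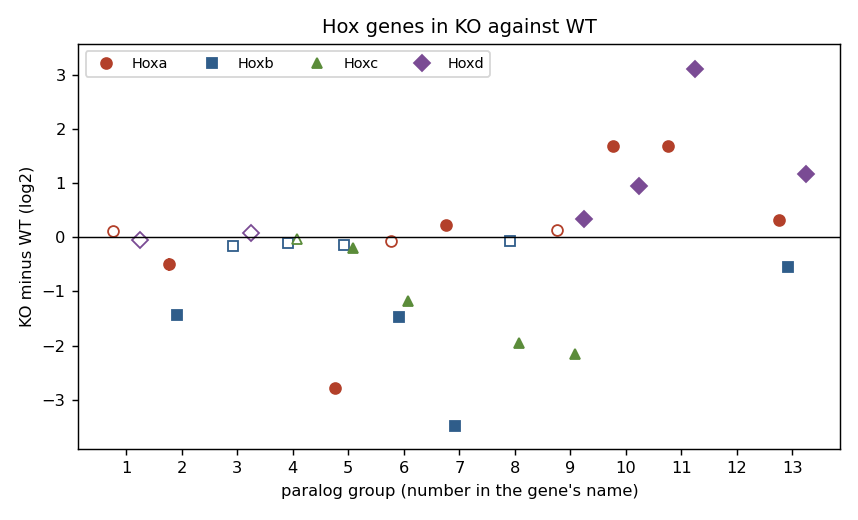
KO minus WT difference in log2 units (vertical axis) of each measured Hox gene by its paralog group (horizontal axis), with marker shape and colour for the 4 clusters, filled markers past the adjusted p threshold of 0.05 and open markers not past it. Bars of 1 SE are shorter than most markers; 6 filled markers lie above 0 in the groups 10 to 13, and 9 lie below 0 in the groups 1 to 9.

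**Figure D3:**
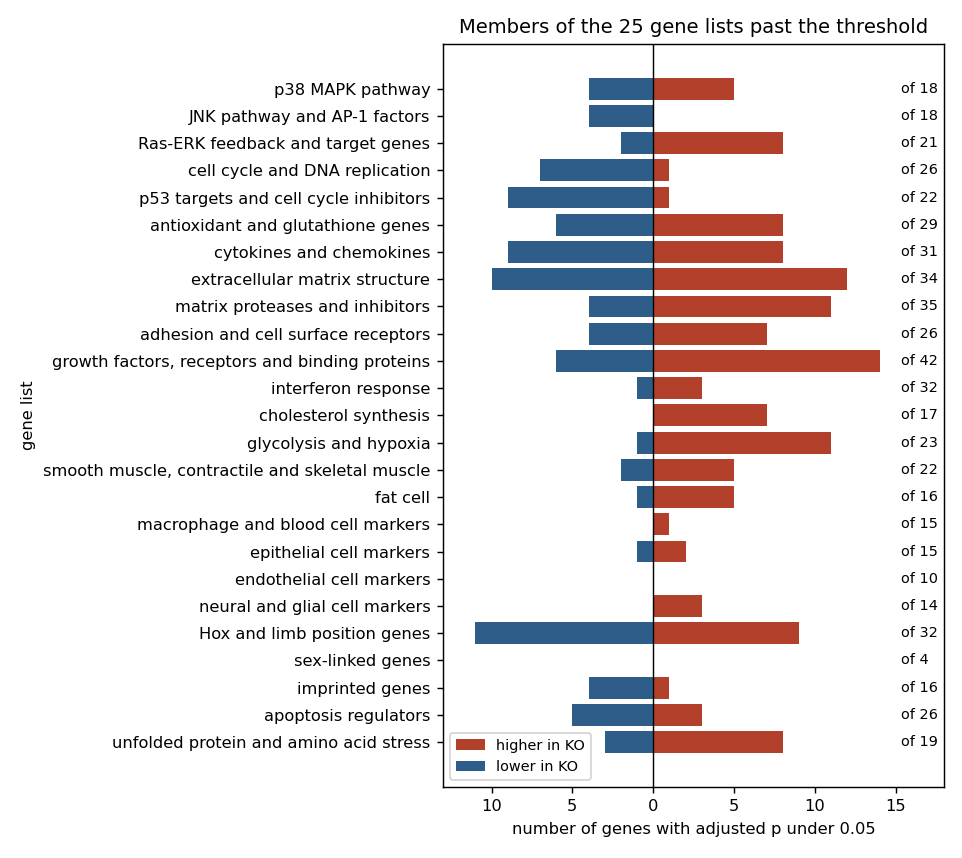
Number of genes past the adjusted p threshold of 0.05 (horizontal axis) in each of the 25 gene lists (vertical axis), with genes higher in KO to the right of 0, genes lower in KO to the left, and the number measured at the right margin. The growth factor list has the most genes higher, 14, and the Hox list the most lower, 11. The number measured includes genes near background on every array.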

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

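The tests on Hba-a1 were chosen after its value was seen. Other splits of the 6 arrays into 3 and 3 called 0 probes in limma after adjustment (134 to 1118 at an unadjusted p under 0.05). KO against WT, 1 of the 10 splits, called 4421 (6054) and was the only split to reach that number. Every other split mixes KO and WT arrays in both of its groups. Their difference then adds to the spread within groups, so few calls were likely beforehand. With 10 splits no share under 0.05 is possible, so they are too few to say whether chance can be excluded.

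Spots masked by the scanner software were left out of the comparison, yet 3 of the 184 gene probes masked on all 6 arrays lay above the 95th percentile of the negative control spots on every array. They were Tgds, with a mean background-subtracted intensity of 113, Pla2g1b with 100.4 and Ttc30a1 with 32.5.

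In the reported fit Hba-a1 was 146-fold higher in KO fibroblasts, a size that depends on the processing. Fibroblasts are not of the red cell lineage. Red blood cell RNA cannot be told apart from activity of the gene in the fibroblasts: the highest of 3 beta-type globin probes on a KO array reached 0.612% of Hba-a1 there, but probes differ in sensitivity and Hbb-bt, the adult beta globin measured, was near background on all 6 arrays. Of 12 other red cell genes, Hbb-bh1, an embryonic beta-type globin, was called higher in KO (at least 1.77-fold, adjusted p = 1.1e-04), Hbb-bt was called higher with both groups near background (adjusted p = 0.042), and Rhag was above background on all arrays without passing. A single aberrant array is argued against, since the log2 difference was at least 7.12 whichever array was left out. Activation of the alpha globin gene in these KO cultures may also give this, as a hypothesis with no independent test, and whether it follows the genotype or a founder line is open.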

How the results depend on the processing

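The spot median, the block on the names inside the files and the counts without KO replicate 3 were chosen after seeing the data. Against 4421 calls, 2047 higher and 2374 lower, normexp with offset 0 gave 2717, with 1331 lower. Median scaling gave 3746, with 1345 lower. The cause was not tested. Offset 0 called 6 antioxidant genes in place of 14, 3 apoptosis genes in place of 8, 7 stress genes in place of 11 and 2 JNK genes in place of 4, and array weights moved the count of cholesterol genes from 7 to 14, imprinted from 5 to 8 and neural from 3 to 5. The 2-fold minimum left 692, 423 higher and 269 lower, by its construction, and also ended the call of Mapk14 (-0.94). Other settings gave 3755 to 5696 calls, the most with array weights, where KO replicate 3 had a weight of 0.242 and the others at least 1.12. Leaving out 1 array gave 3191 to 5826 calls, 1529 to 2669 higher and 1662 to 3157 lower, and for Mapk14 -0.98 to -0.88, against -2.24 to -0.80 over the other settings. Of 69 called genes named here and measured in both groups, the log2 differences of 7 moved by over 1.5 times with offset 0 and of 11 with the authors' table, all of them larger, and of 3 under median scaling. The naming rules gave 32 more called genes with a group below background. Of those, 29 moved by over 1.5 times with offset 0, all of them larger. No call shared between a setting and the reported fit changed sign.

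Of 24 lists tested, 3 passed camera as reported and 0 with an estimated correlation (3 at an unadjusted p under 0.05). The estimated correlations of these 3 lists were -0.017 for glycolysis and hypoxia, -0.039 for p53 targets and 0.0085 for cholesterol synthesis. All lie below the preset 0.01, which argues against a higher correlation between genes as what ended these 3 calls. With an estimated correlation, camera also takes its degrees of freedom from the arrays in place of the genes, a stricter test with 6 arrays. For cholesterol synthesis the unadjusted camera p rose from 2.2e-04 to 0.020 between the 2 forms. Losing these calls therefore does not by itself speak against the lists. Of 21 lists, 0 passed with the authors' values (6 at an unadjusted p under 0.05), and the cause was not tested. There the same 3 lists and the matrix proteases had an adjusted p of 0.052. Leaving out 1 array gave 2 to 4 lists passing camera. Over the 105 named genes other than Mapk14 and every alternative, 1828 of 1877 values kept direction and side of the threshold, 43 lost their call, 27 of them under the 2-fold minimum, and 5 gained one. Eif2s3x, not called, changed sign without KO replicate 1 (-0.018, with 0.145 the highest value with 1 array left out; the cause was not tested).

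Deviations from the group means correlated across probes at 0.24, -0.12 and 0.10 for the titles' replicate numbers 1, 2 and 3. By the numbers inside the files these values were 0.24, 0.20 and -0.087. Neither numbering shows a pairing at all 3 numbers, and whether any cultures were paired is open. With the replicate number as a block, 4333 probes were called and the p53 list (0.051) and Lamb3 (0.053) missed the threshold, and 4564 with the numbers inside the files. Not run were the Cy3, ratio and 2-channel fits and loess (the files hold 1 channel), and slide or scan day as a block (all arrays share the day). Quantile normalization without loess is the setting reported. Signal over background limits 8733 probes near background on every array.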

Other observations

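The tests on the Hox genes, the bootstrap interval, the medians of the brighter genes and the genes named in the next paragraph were chosen after the results were seen.

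Among list members not described above, Thbs2, the matricellular protein thrombospondin 2, was 7.01-fold higher in KO (adjusted p = 9.7e-06), and Fbn1, fibrillin 1, 3.25-fold. Serpinf1, a non-inhibitory serpin, was 4.58-fold and Timp1, an inhibitor of metalloproteinases, 4.53-fold higher. Bmp4 was 4.12-fold and Tgfb1 2.31-fold higher, while Ccn1 and Ccn2, a pair of matricellular genes of the same family as Ccn3, were 2.70-fold and 2.35-fold lower. Each of these had an adjusted p of 8.11e-04 or smaller.

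Of the Hox genes called, those of the paralog groups 10 to 13 were mostly higher (6 higher, 1 lower) and those of the groups 1 to 9 mostly lower (9 lower, 2 higher, and 10 more that did not pass), a division seen in the same genes and therefore not tested here. Among these calls, Hoxc5 was near background in both groups, and Hoxa13 and Hoxd9 were too close to it for a fold bound. Scaling is argued against, since all 18 called Hox genes kept direction and call under median scaling; with offset 0 all kept their direction and 14 their call. A different body position of the founding cells may also give such a division. Of 6 measured position genes outside the clusters, 3 passed, Meis1 (-1.57), Meis2 (-1.55, above background in 2 of 3 KO cultures) and Tbx15 (0.95), and the other 3, Emx2, Pitx1 and Tbx4, were near background in both groups. With 1 pool identifier per genotype, and WT pools whose names differ in their last member, position cannot be told apart from an effect of the genotype.

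Genes of the same chromosome tended to shift together. Over 6012 detected genes, the median difference departed from the rest on 13 of 20 chromosomes (permutation test over genes, Benjamini-Hochberg over 20), lower in KO on 7 and higher on 6, with the same sign under 4 other settings for all 13. Chromosome 18 lay at -0.20, with 62 genes lower and 18 higher, chromosome 3 at -0.20 and the X at 0.16 (each adjusted p = 0.00025, from a permutation p of 1e-04, the smallest that 10000 permutations can give). A limit of 0.3 set beforehand for a copy number difference was not reached. The offset shrinks differences of dim genes, however, and with offset 0 chromosome 18 lay at -0.299, with a 95% bootstrap interval of -0.37 to -0.19 that spans the limit (-0.33 among the brighter genes). A difference in chromosome dose between the cultures may therefore contribute and cannot be told apart from shared regulation, since no DNA was measured and genes of a chromosome are not independent.

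Near Mapk14, 16 of the 60 nearest measured genes were called. In 8894 windows on other chromosomes the median was 16 and the 95th percentile 22. This argues against an excess over the whole window from flanking DNA of the knockout allele. Such a count cannot address an effect limited to the closest genes. The measured genes directly beside Mapk14, Srpk1 (-0.35, limma adjusted p = 0.028) and Mapk13 (-1.23, 4.3e-04), were both called lower. Of the 16, 5 were higher and 11 lower. They include Srpk1, Mapk13, Cdkn1a and Dusp1, for which an effect of that DNA is not excluded. Among the brightest 6478 probes the spread of KO replicate 3 around the other KO arrays was 2.29 times theirs (95% bootstrap interval 1.81 to 2.78), above the limit of 1.5 set for background alone.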
